A study of Mus musculus with 8 samples.

How the data were processed

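Peritoneal macrophages of mice that lack the LDL receptor (Ldlr-/-) had been kept in serum-containing medium, and poly(A)-enriched RNA was sequenced from 8 libraries, per the labels' protocols. The titles put 4 libraries in an untreated control group and 4 in a group treated with recombinant mouse PCSK9, the secreted protein that binds the LDL receptor and sends it to the lysosome, and number the libraries 1 to 4 within each group. The dose, the duration, the source of the protein and any vehicle are not given in the sources used here. Nothing in the labels says whether the libraries of a group came from separate mice or separate cultures, so the p-values measure the spread between these libraries, part of which may be technical.

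The authors deposited 1 table for the whole series with 17823 gene symbols and 8 value columns, and the column names gave the group and the replicate number of each library. The deposited values are a normalized signal per gene, made with DESeq2 on the mm10 genome build per the submitters' processing notes. The aligner, the gene annotation, the read counter and its handling of strand are not given in the sources used here. In each column every positive value was a whole multiple of 1 step, within 0.01 of a read for 100% of positive values, so the signal is a read count divided by a size factor for the library. The value of 1 read lay between 0.8948 and 1.075. Dividing by it gave implied totals of 18068687 to 21263385 reads per library, and between 14118 and 15005 genes stood above 0. A mean near 10 thus rests on about that many reads per library, and counting error is large for such genes. Of the symbols, 963 stood at 0 in all 8 libraries. The list of mitochondrially encoded genes had no matching symbols and was not analysed here.

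The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(deposited value + 1) for the genes with a mean of at least 10 over the 8 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is the difference between the group means on the log2(value + 1) scale, which understates the change of genes near 0. The choice of test, the filter, the alternatives, 42 gene lists and the rule for naming genes were fixed before the data were examined. Lists covered inflammatory signalling, macrophage identity, lipid handling, RNA quality and the other cell types a peritoneal lavage could hold. Of their 823 symbols, 767 matched the table directly, 8 matched under an older symbol such as Irg1 for Acod1, and 48 did not match. Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 37 lists tested. Camera was also run with an estimated correlation, and fry was run beside it.

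The text names the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold with a mean of at least 50 and no overlap between the groups. It also names up to 4 called members of each list with a mean of at least 50, or up to 2 of the most abundant members where none was called, and Ldlr, Pcsk9, Lrp1, Lrp8, Vldlr, Cd36, Olr1 and Tlr4 in every case. Genes outside this rule are said to be so where they appear.

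Replicate numbers were checked for pairing before calls were compared. Deviations from the group means correlated across genes at 0.69, 0.42, 0.52 and 0.51 for the control and PCSK9 libraries numbered 1, 2, 3 and 4, and each control library correlated best with the PCSK9 library of its own number. The numbers were therefore taken to pair the libraries, from the data and not from a statement in the labels. The main design had no block, as fixed beforehand, and the fit with the replicate number as a block is given beside a result where it changed the call or moved a count by over 1.5 times.

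Alternatives covered pseudocounts of 0.5 and 5, no filter and a mean of at least 50, an own implementation of TMM scaling, quantile normalization, median centring, limma arrayWeights, limma without the trend, the replicate block and each library left out. Fits with the block and 1 replicate number left out, and a fit with the log2 share of the ribosomal RNA precursor Rn45s as a covariate, were added after the data had been seen. The test was checked on simulated values for the 11557 genes tested. Without the block it recovered 79 of 100 genes changed 1.5-fold and 99 of 100 changed 3-fold, with 1 false call among 186. With the block it recovered 97 and 100, with 18 false calls among 234. Simulated spread was a smooth function of the mean, the form the variance trend assumes, and changed genes had means of at least 50. These rates therefore do not cover genes whose spread departs from that trend, or changed genes with means under 50. Of 200 simulated lists without a change, 0 had a camera p under 0.05. The simulated genes varied independently of each other, whereas the estimated correlation within the real lists reached 0.79. The simulation therefore could not check camera on lists whose members vary together. Gene coordinates came from the GENCODE annotation of mm10. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.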

Results

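Gene expression was measured by poly(A)-enriched RNA sequencing in Ldlr-/- mouse peritoneal macrophages, phagocytes collected from the abdominal cavity, in 4 untreated control libraries and 4 libraries treated with recombinant mouse PCSK9. PCSK9 is best known for lowering LDL receptors on the surface of liver cells, and the series title ties it to lesions of vein grafts. The comparison asked how the transcriptome of macrophages without a functional LDL receptor differed when PCSK9 was added. Implied totals were 21263385, 18068687, 20093014 and 18445330 reads in control libraries 1 to 4 and 20593941, 18518222, 18871703 and 18334269 reads in PCSK9 libraries 1 to 4. Values below are the deposited read counts divided by a size factor, called normalized counts, as mean ± SD with n = 4 per group.

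Ldlr itself (chromosome 9, 21723483 to 21749919 on mm10, plus strand) lay between 8082 and 12505 normalized counts in all 8 libraries, at 11500 ± 1293 in controls and 11070 ± 2021 with PCSK9. A count over the whole gene cannot show which part of a transcript is disrupted, so it does not check the genotype. Its log2 fold change of -0.07 ± 0.14 (SE) did not pass the test (limma adjusted p = 0.89). Pcsk9 transcripts were scarce, at 7.83 ± 4.96 in controls and 7.08 ± 4.56 with PCSK9, below the filter for testing.

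Inflammatory genes led the rises in PCSK9-treated macrophages. The largest were those of Il1b, which encodes the cytokine interleukin-1 beta, and Irg1 (Acod1), which encodes the enzyme that makes itaconate. Il1b stood at 2.55 ± 1.37 in controls and 177 ± 96.7 with PCSK9, and Irg1 at 31.3 ± 11.96 and 1537 ± 591. The neutrophil chemoattractants Cxcl1 and Cxcl2 rose from 5.51 ± 5.05 to 99.9 ± 39.7 and from 31.5 ± 20.3 to 534 ± 200. Olr1, which encodes the oxidized LDL receptor LOX-1, rose 10.8-fold from 35.1 ± 3.80 to 407 ± 150. The pattern-recognition receptor gene Tlr2 rose 4.75-fold from 216 ± 59.9 to 1012 ± 198.

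Of 11557 genes tested, 111 were higher and 17 were lower with PCSK9 at a limma adjusted p under 0.05. All 128 had no overlap between the groups, which by itself fixes the same direction in 4 of 4 replicate pairs. Such separation was found for 894 tested genes, or 7.74%, against 2.86% by chance for 4 libraries against 4. A change of at least 2-fold was found for 50 of the higher genes and 0 of the lower genes. With the replicate number as a block, limma called 834 genes higher and 679 lower, including all 128, of which 66 and 5 changed at least 2-fold. Without the block, the count of higher genes was 51, 57 and 60 when control library 1, 2 or 3 was left out, and 45 and 62 without PCSK9 library 1 or 2. In the 8 fits with 1 library left out, Ldlrap1 and Rab40c lost their calls in all 8, Bcl2a1a, Cd83, Chac1, Gpr146, Maff, Slc7a11, Tifab and Ubald1 in 7, Acsl1, Cebpa, Fgr, Mnt, Nfkbid, Nlrp3, Tnfsf15 and Tnip3 in 6, and Ccl5, Cxcl1, Icam1, Nfkb1, Sik1, Tnf and Tnfaip8l2 in 5. Without the variance trend limma called 62 genes higher and 2 lower, and of the named genes Cxcl1, Marcksl1, Tnf, Icam1, Tnip3, Nfkb1, Nlrp3, Fgr, Ccl5 and Bcl2a1a lost their calls (limma adjusted p from 0.0617 for Bcl2a1a to 0.123 for Nlrp3), as did Cebpa, Sik1, Tifab, Tnfaip8l2, Mnt, Gpr146, Ubald1 and Nfkbid (0.0621 for Sik1 to 0.115 for Mnt). With quantile normalization Bcl2a1a and Hspa1a lost theirs (0.0726 and 0.0708). With the log2 Rn45s share of each library as a covariate, added after the data had been seen, 66 genes were higher and 4 lower, and the named genes Cxcl1, Tnfsf15, Ccl5, Nfkb1, Nlrp3, Fgr, Ifi205, Chac1, Hspa1a, Acsl1, Slc7a11, Cd83, Maff, Sik1, Tifab, Tnfaip8l2, Mnt, Gpr146, Ubald1, Rab40c, Ldlrap1 and Nfkbid lost their calls (limma adjusted p from 0.0565 for Tnfaip8l2 to 0.14 for Ldlrap1). The count of lower genes without the block was 2, 3, 3 and 7 without control library 1, 2, 3 or 4, and 3 and 2 without PCSK9 library 1 or 2.

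The 12 genes with the largest rises ranged from 47.8-fold for Il1b to 4.63-fold for Mefv, which encodes the inflammasome protein pyrin. Irg1 on chromosome 14 (103046977 to 103056573, plus strand) had the smallest adjusted p, with a log2 fold change of 5.57 ± 0.30 (SE, limma adjusted p = 8.8e-05). Il1b on chromosome 2 (129364570 to 129371139, minus strand) had a log2 fold change of 5.58 ± 0.42 (limma adjusted p = 0.000433). Olr1 on chromosome 6 (129485244 to 129507165, minus strand) had one of 3.44 ± 0.23 (limma adjusted p = 0.000338). Cxcl1 and Cxcl2 lie close together on chromosome 5, starting at 90891241 and 90903871, and rose 20.1-fold and 17.5-fold. Gpr84, a receptor for medium-chain fatty acids, rose 12.1-fold, and Gbp5, an interferon-induced GTPase, rose 8.99-fold. The membrane protein gene Flrt3 and the actin regulator Marcksl1 rose 5.76-fold and 5.68-fold. Clec4e, which encodes the C-type lectin Mincle, rose 5.03-fold. Control means of Il1b, Cxcl1 and Gpr84 lay under 10, so their folds on the log2(value + 1) scale are imprecise. With pseudocounts of 0.5 and 5 the fold was 56.9 and 22.0 for Il1b and 25.1 and 10.2 for Cxcl1.

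**Figure D1:**
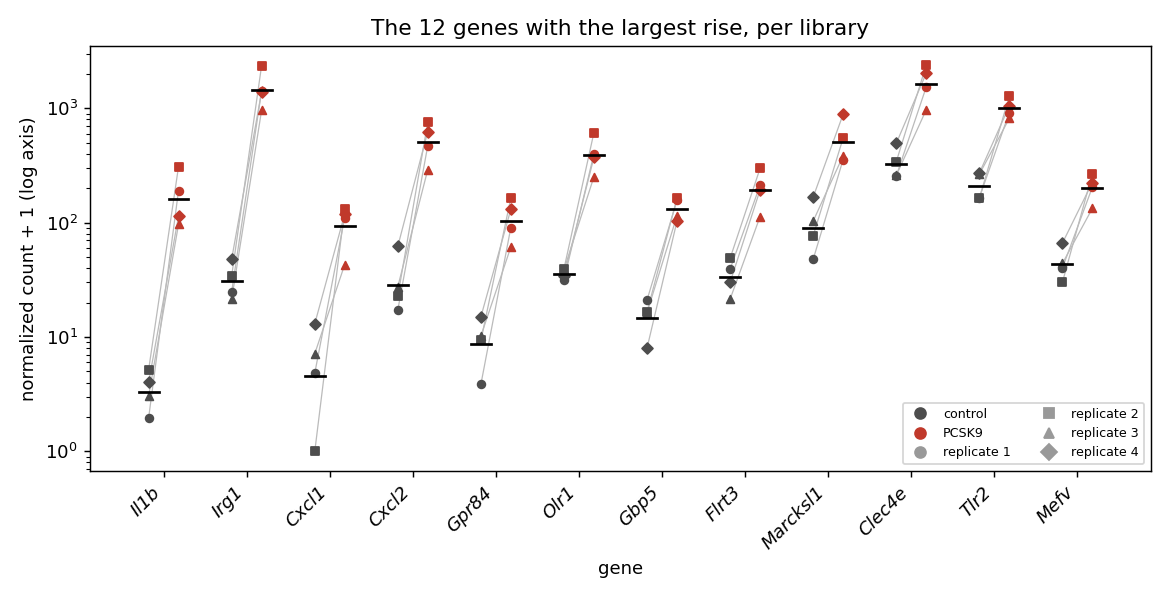
Normalized count plus 1 (log axis) of the 12 genes with the largest rise, with 4 control (grey) and 4 PCSK9 (red) libraries per gene, symbols for the replicate number, lines joining libraries of the same number and black bars for the mean on the log scale. Every PCSK9 library lies above every control library for each gene, as the naming rule required. Il1b stood at 2.55 in controls and 177 with PCSK9 on average.

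Factors and feedback inhibitors of NF-κB, the transcription factor family of inflammatory signalling, formed the list with the smallest p. Of 18 tested members 12 rose and 1 fell, and 16 rose and 1 fell adjusted over the list alone, with a list median log2 fold change of 0.87 (camera adjusted p = 8.73e-21, adjusted p = 0.173 with an estimated correlation). The inhibitors Nfkbie and Nfkbia rose 4.32-fold and 3.80-fold, and Nfkbiz, an atypical member of the inhibitor family, rose 3.54-fold. Tnip3, which restrains the pathway, rose 3.03-fold. Relb, Nfkb2 and Nfkb1, which encode subunits of the factor and were chosen after their values were seen, rose 2.37-fold, 2.05-fold and 1.48-fold. Nfkbid, another atypical member of the inhibitor family, was the list member that fell (0.785-fold).

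Proinflammatory cytokines had 3 of 7 tested members higher, and 4 adjusted over the list alone, and the call held with an estimated correlation without the block but not with it (camera adjusted p = 1.84e-07, adjusted p = 0.0413 with an estimated correlation, and 0.311 with both the block and an estimated correlation). Tnf, the gene of tumour necrosis factor, rose 3.87-fold from 342 ± 79.4 to 1419 ± 664, and Tnfsf15 rose 2.92-fold. Chemokines had 3 of 13 higher, and 5 adjusted over the list alone, with Ccl5 at 6.68-fold beside Cxcl1 and Cxcl2 (camera adjusted p = 2.98e-06, adjusted p = 0.511 with an estimated correlation). Effectors of classical macrophage activation had 3 of 19 higher, and 8 adjusted over the list alone (camera adjusted p = 1.35e-08, adjusted p = 0.173 with an estimated correlation). Beside Irg1 these were the adhesion molecule Icam1 at 2.80-fold and Sod2, mitochondrial superoxide dismutase, at 1.72-fold. With the block, 5 cytokines, 7 chemokines and 11 activation effectors were higher and 1 chemokine was lower. Tnfsf15 and Ccl5 had means under 50 and were chosen after their values were seen.

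Interferon-stimulated genes had 4 of 32 tested members higher, and 9 adjusted over the list alone (camera adjusted p = 2.98e-06, adjusted p = 0.67 with an estimated correlation). Gbp5, Ifit1 (3.22-fold), Gbp2 (1.72-fold) and Ifi205 (10.4-fold, chosen after its values were seen) were the members that rose, and Ifi205 was 14.1-fold and 4.32-fold higher with pseudocounts of 0.5 and 5. Toll-like receptors and their adaptors had 2 of 21 higher, Tlr2 and the adaptor Ticam2 (1.31-fold), and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000391, adjusted p = 0.173 with an estimated correlation). Inflammasome genes had 2 of 14 higher, the sensor Nlrp3 (2.29-fold) and the caspase gene Casp4 (1.84-fold), and 5 adjusted over the list alone (camera adjusted p = 0.00292, adjusted p = 0.173 with an estimated correlation). Syk and ITAM signalling had 2 of 23 higher, Clec4e and the Src-family kinase gene Fgr (1.44-fold), and 4 adjusted over the list alone (camera adjusted p = 0.0238, adjusted p = 0.554 with an estimated correlation). Without PCSK9 library 2 the Syk and ITAM list did not pass (camera adjusted p = 0.0799). With the block, 12 interferon-stimulated genes, 11 Toll-like receptor genes, 5 inflammasome genes and 9 Syk and ITAM genes were higher, and 1, 1, 0 and 2 were lower.

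Apoptosis and necroptosis genes had 5 of 27 tested members higher, and 6 adjusted over the list alone (camera adjusted p = 0.00816, adjusted p = 0.183 with an estimated correlation). The death receptor gene Fas rose 2.51-fold, and the other members that rose, Birc3 (1.85-fold), Bcl2a1d (1.82-fold), Cflar (1.51-fold) and Bcl2a1a (2.58-fold, chosen after its values were seen), encode inhibitors of cell death. With the block 9 were higher and 5 lower, and the list did not pass with the block and without replicate number 1 (camera adjusted p = 0.0713). The unfolded protein response list had 2 of 26 higher, and 3 adjusted over the list alone (camera adjusted p = 0.00167, adjusted p = 0.511 with an estimated correlation). These were Herpud1 (1.85-fold), a component of endoplasmic reticulum protein degradation, and Chac1 (4.85-fold, chosen after its values were seen), which degrades glutathione and was 5.28-fold and 3.17-fold higher with pseudocounts of 0.5 and 5. With the block 9 were higher and 1 lower, and the list did not pass with the block and without replicate number 3 (camera adjusted p = 0.0671). Heat shock genes had 1 of 12 higher, Hspa1a at 2.33-fold (chosen after its values were seen), and 2 adjusted over the list alone (camera adjusted p = 0.0438, adjusted p = 0.46 with an estimated correlation). In the blocked fit 2 heat shock genes were higher and 1 was lower. With the block the heat shock list did not pass (camera adjusted p = 0.0688, and 0.123, 0.0633 and 0.128 without replicate number 1, 3 or 4), nor did it without control library 1 or 3 (0.0715 and 0.0781), without PCSK9 library 1 or 4 (0.0658 and 0.123), with a mean of at least 50 required (0.5) or with the Rn45s covariate (0.174). With fry in place of camera, the lists of chemokines, unfolded protein response and heat shock (fry adjusted p = 0.111 each), Syk and ITAM signalling (0.126) and interferon-stimulated genes (0.283) did not pass. With both fry and the block, the interferon-stimulated and heat shock lists passed (fry adjusted p = 0.0148 and 0.0462). The chemokine, Syk and ITAM, and unfolded protein response lists did not (0.0542, 0.0762 and 0.141). Bcl2a1a, Bcl2a1d, Hspa1a, Ifi205, the Gbp genes, Cxcl1 and Cxcl2 have near-identical or related copies, so their separate values are uncertain where reads were shared.

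**Figure D2:**
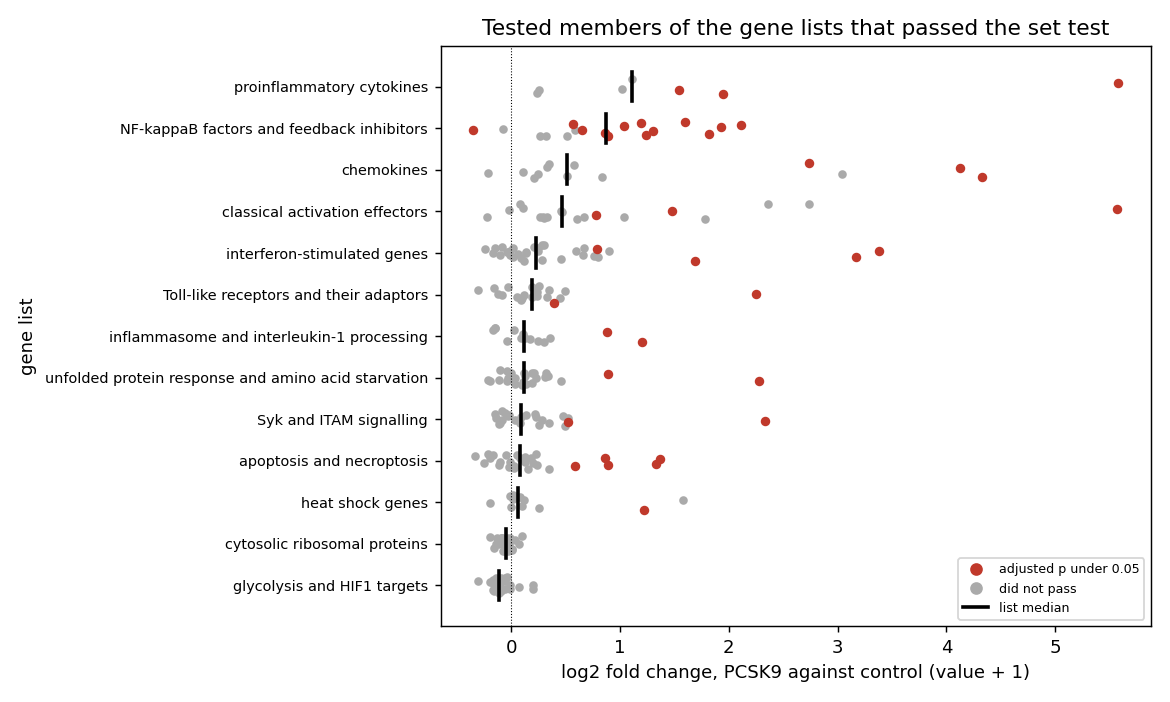
Log2 fold change of PCSK9 against control for each tested member (1 point per gene) of the 13 lists that passed the camera test, with red points for genes at an adjusted p under 0.05 and black bars for list medians. Proinflammatory cytokines have the highest median, 1.11, and the ribosomal protein and glycolysis lists have medians of -0.05 and -0.11.

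Receptors linked to PCSK9 did not move together. Among scavenger and LDL-receptor-family receptors 1 of 20 tested members rose, Olr1, with 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.931). With the block 4 members were higher and 3 lower. Lrp1, an endocytic receptor, stood at 96460 ± 8820 in controls and 85450 ± 8247 with PCSK9 (log2 fold change -0.18 ± 0.11, limma adjusted p = 0.566, 0.00373 with the block). Cd36, a receptor for oxidized LDL and fatty acids, stood at 109300 ± 14440 and 119600 ± 17380 (0.13 ± 0.13, limma adjusted p = 0.745, 0.0225 with the block). Tlr4, the receptor for bacterial lipopolysaccharide, stood at 1203 ± 85.5 and 1431 ± 190 (0.24 ± 0.09, limma adjusted p = 0.357, 0.00567 with the block). Lrp8 stood at 243 ± 61.1 and 262 ± 51.6, and Vldlr at 14.2 ± 8.44 and 14.7 ± 13.4. Neither passed with or without the block.

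Lipid metabolism lists did not pass. Cholesterol synthesis had 0 of 22 tested members called and 0 adjusted over the list alone (camera adjusted p = 0.769), with Cyp51 at 5411 ± 387 in controls and 5760 ± 330 with PCSK9 and Srebf2, the gene of the SREBP2 regulator, at 5867 ± 337 and 5474 ± 606. Cholesterol efflux and LXR targets had 0 of 16 called and 0 adjusted over the list alone (camera adjusted p = 0.819), with Apoe at 39080 ± 10620 and 34610 ± 5474. With the block, 1 synthesis gene was higher, and 2 efflux genes were higher and 1 lower. Acsl1, which activates fatty acids, was the single called member among 23 genes of fatty acid synthesis and storage (1.22-fold, 1 adjusted over the list alone, camera adjusted p = 0.769 for the list), and with the block 2 were higher and 4 lower. Other called genes from lists that did not pass included the cystine transporter Slc7a11 (1.65-fold), the protease Adam17 (1.41-fold), which releases tumour necrosis factor, Cd83 (1.75-fold), the cytokine signalling inhibitor Socs3 (2.03-fold) and the transcription factor Maff (2.09-fold). Acsl1, Adam17, Slc7a11, Cd83 and Maff lost their calls without the variance trend (limma adjusted p = 0.0764, 0.0518, 0.123, 0.116 and 0.0966), and Maff also with quantile normalization (0.0504).

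Genes that were lower with PCSK9 changed little in size. The 12 largest falls ran from 0.706-fold for Aatk, a membrane kinase (651 ± 27.3 in controls, 460 ± 33.3 with PCSK9, log2 fold change -0.50 ± 0.07, limma adjusted p = 0.00882), to 0.785-fold for Nfkbid, described above with the NF-κB list. Cebpa, a transcription factor of myeloid differentiation, stood at 4573 ± 194 and 3330 ± 380 (0.725-fold). The kinase genes Mast3 and Sik1 stood at 0.754-fold and 0.761-fold, and Tifab, an inhibitor of TRAF signalling, at 0.756-fold. Tnfaip8l2, a negative regulator of innate immunity, stood at 0.771-fold, and Mnt, a transcriptional repressor, at 0.773-fold. Gpr146, Ubald1 and Rab40c stood at 0.767-fold, 0.767-fold and 0.777-fold. Ldlrap1, the adaptor that carries the LDL receptor into clathrin-coated pits, stood at 4665 ± 319 and 3658 ± 253 (log2 fold change -0.35 ± 0.07, limma adjusted p = 0.0462). Its call ended with TMM scaling (limma adjusted p = 0.0521), with quantile normalization (0.0513), without the filter (0.0556), without the variance trend (0.123) and when any 1 library was left out. Rab40c lost its call with TMM scaling (limma adjusted p = 0.0521), without the trend (0.0923) and when any 1 library was left out.

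Cytosolic ribosomal proteins and glycolysis genes passed as lists in the lower direction without any called member. The ribosomal list had a median log2 fold change of -0.05 over 34 tested members with 0 adjusted over the list alone (camera adjusted p = 0.0118, adjusted p = 0.946 with an estimated correlation), with Rplp0 at 9214 ± 554 in controls and 8680 ± 526 with PCSK9. The glycolysis and HIF1 list had a median of -0.11 over 27 tested members with 0 adjusted over the list alone (camera adjusted p = 0.0172, adjusted p = 0.67 with an estimated correlation), with Aldoa at 25180 ± 1256 and 23710 ± 1160 and Pkm at 31680 ± 3535 and 29790 ± 3026. With quantile normalization neither passed (camera adjusted p = 0.109 and 0.0751), and with the block 2 ribosomal genes were lower, and 2 glycolysis genes were higher and 5 lower. The ribosomal call also ended without control library 2 or 4 or PCSK9 library 3 (camera adjusted p = 0.204, 0.194 and 0.0986) and with the block without replicate number 4 (0.147), and the glycolysis call without control library 4 or PCSK9 library 1 (0.29 and 0.0658). With fry neither passed (fry adjusted p = 0.715 and 0.388). The lysosome list did not pass (camera adjusted p = 0.103) but was lower with the block (0.00441) and without control library 2 or 4 or PCSK9 library 1 or 3 (0.0391, 0.0117, 0.0444 and 0.0158), and the block called 1 member higher and 4 lower, with Ctsd at 295200 ± 37570 and 273100 ± 49280 and Psap at 382200 ± 62240 and 353100 ± 67410. With an estimated correlation the lysosome list did not pass without or with the block (camera adjusted p = 0.946 and 0.702), nor with fry (fry adjusted p = 0.791 and 0.0762), and with the Rn45s covariate its direction turned to higher (camera adjusted p = 0.806). The remaining lists of the 24 that did not pass had camera adjusted p values from 0.0564 for cell cycle genes to 0.947 for fibroblast markers. The median, the mean and the test differed in sign for the lists of scavenger receptors, immediate early genes, NRF2 targets, endothelial cells, complement and Fc receptors, cholesterol efflux and fibroblasts, and none of these passed.

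Markers of other cell types did not pass as lists, and the lists of T and NK cells, eosinophils, mast cells and basophils, and erythroid cells and platelets had fewer than 3 members above the filter and were not tested. B cell markers had 0 of 6 tested members called (camera adjusted p = 0.555), with Cd22 at 1270 ± 435 in controls and 1187 ± 413 with PCSK9. Among macrophage markers 0 of 12 were called (camera adjusted p = 0.819), with Mpeg1 at 97040 ± 4255 and 93670 ± 2496. With the block 2 were higher, Cd14 (1.18-fold) and Csf1r (1.11-fold), and 2 were lower, Mafb (0.812-fold) and Mertk (0.875-fold), 4 genes chosen after their values were seen (limma adjusted p = 0.0241, 0.0246, 0.00674 and 0.0397 with the block, and 0.601, 0.48, 0.64 and 0.777 without it). Dendritic cell markers had 0 of 6 called (camera adjusted p = 0.385), and Irf8, a transcription factor of monocytes and dendritic cells, stood at 2722 ± 258 and 1991 ± 350 (0.726-fold, limma adjusted p = 0.13, 0.0424 with arrayWeights, 3.81e-05 with the block). Fibroblast markers had 0 of 11 called, with Col1a1 at 829 ± 438 and 721 ± 425 (limma adjusted p = 0.91, 0.0349 with the block). Mesothelial markers had 0 of 8 called and a list median of 0.73 (camera adjusted p = 0.474), which followed 1 library. Krt7 stood at 436 and Krt8 at 398 in PCSK9 library 4, against at most 22.1 and 26.0 in the other 7 libraries. Without PCSK9 library 4, limma called 85 genes higher and 12 lower, of which 79 and 7 were among the 111 and 17.

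The 45S ribosomal RNA precursor Rn45s took 9.07%, 2.84%, 8.58% and 1.73% of the total in control libraries 1 to 4 and 1.09%, 1.87%, 8.28% and 1.03% in PCSK9 libraries 1 to 4. It was lower with PCSK9 in 4 of 4 pairs, at a mean of 5.56% ± 3.81 in controls and 3.07% ± 3.50 with PCSK9. The difference did not pass a two-sided exact permutation test (p = 0.2), and the exact sign-flip test of the pairs gave p = 0.125, the smallest that 4 pairs allow, so that test could not pass. Limma with the block did call Rn45s lower (log2 fold change -1.17 ± 0.34, adjusted p = 0.0438, against 0.612 without the block). Implied read totals differed by less than the spread between libraries (exact permutation p = 0.771). In the 4 pairs the 111 higher genes had median log2 ratios of 0.95, 1.11, 0.62 and 0.81, and the 17 lower genes had medians of -0.35, -0.39, -0.27 and -0.40.

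**Figure D3:**
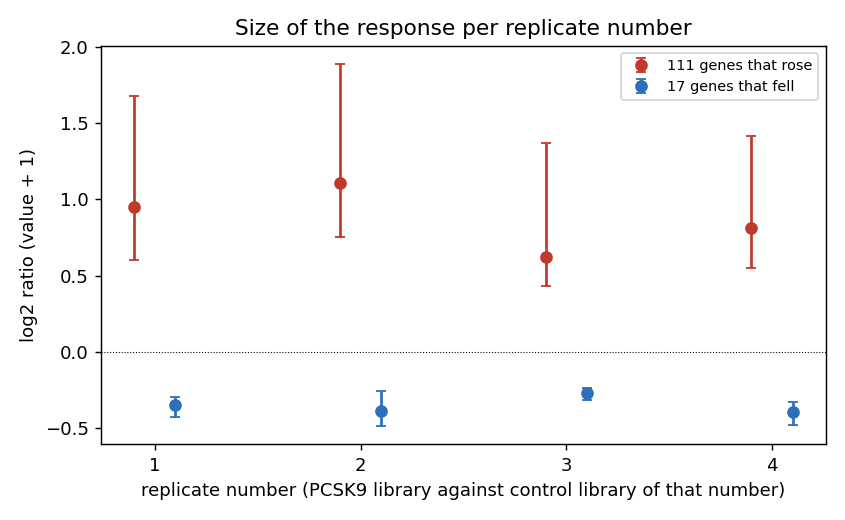
Log2 ratio of the PCSK9 library to the control library of the same replicate number, with points for the median and bars for the interquartile range over the 111 genes that rose (red) and the 17 that fell (blue). The median rise lies between 0.62 in pair 3 and 1.11 in pair 2.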

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

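The fit with the Rn45s share and the reading of genes in a left-out pair were added after the main result was seen, and the other tests of this part were chosen before.

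A library far from the other 3 of its group was found in 18 of 194 groups of 4 by Dixon's ratio of gap to range, on the log2 scale for genes. Chance gives about 1 in 20 for independent groups, but these groups share libraries that pair by number. Some of the genes were chosen after their values were seen, Plin2, Fpr2 and Tfeb among those flagged. Several of the flagged libraries came in pairs. Cd36 stood at 130995 in control library 4 against at most 102447 in the other controls (ratio 0.972), and at 145640 in PCSK9 library 4 against at most 111521 (0.955). Ldlr stood at 9570 in control library 4 against at least 12069 (0.925) and at 8082 in PCSK9 library 4 against at least 11682 (0.844). Plin2, a lipid droplet gene, stood at 23048 in control library 4 against at least 27443 (0.896) and at 18797 in PCSK9 library 4 against at least 24735 (0.901). Col1a1 stood at 190 in control library 1 against at least 954 (0.881) and at 108 in PCSK9 library 1 against at least 816 (0.876).

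In replicate 4 alone of its group, Fgr stood at 2352 in control library 4 against at most 1932 (0.935), Tifab at 2805 against at most 2528 (0.866) and Tfeb at 1417 against at least 1653 (0.843). In PCSK9 library 4, Cyp51 stood at 5267 against at least 5887 (0.909), Mast3 at 1585 against at least 1723 (0.838) and Fpr2 at 56.4 against at most 29.5 (0.874). Birc3 stood at 660 in control library 2 against at most 602 (0.934), and Lrp8 at 339 in PCSK9 library 2 against at most 243 (0.846). Cxcl1 stood at 41.9 in PCSK9 library 3 against at least 109 (0.84). The Rn45s share was 8.28% in PCSK9 library 3 against at most 1.87% in the other PCSK9 libraries (0.884).

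The 111 genes that were higher with PCSK9 could come from a chance arrangement of the libraries or from the unequal ribosomal RNA share, rather than from the treatment. Of the 35 splits of the 8 libraries into 4 and 4, 1 called as many genes, the real one, with 128. The highest other called 75 and kept every pair together. Such a count excludes chance only if the libraries are exchangeable, and their pairing by number speaks against that. The 8 splits that part all 4 pairs (highest other 0) are too few for a share under 0.05, so the splits cannot exclude chance. The log2 Rn45s share was then added as a covariate, a test chosen after the response and the pairs had been seen. The median log2 rise was 0.87 with it and 0.89 without it (median SE 0.13 in both). All 111 kept their direction and 62 kept their call, the others losing it in a fit with fewer residual degrees of freedom. The median passed the bound of 0.1, set before that fit was run, by less than the interquartile range of 0.97. That range is the spread between genes, and the rise without the covariate (quartiles 0.57 and 1.57) would have missed it too, so this rule could not decide. With the covariate the quartiles were 0.54 and 1.5, both above the bound. That reading was chosen after the fit, on genes picked for their rise in the same libraries, so it does not exclude the share. It shows only that a linear adjustment for the share changed the median rise of these genes little. Genes picked in the blocked fit without a pair had median log2 ratios of 0.39, 0.44, 0.21 and 0.31 in the left-out pairs 1 to 4, over different sets of 411, 480, 683 and 660 genes, against Rn45s differences of -7.98, -0.97, -0.3 and -0.7 percentage points, so the smallest difference went with the smallest median but the largest did not go with the largest, and 4 pairs are too few to decide whether the share made a part of the rise. Left open too is a bacterial ligand carried with the added protein, because 0 libraries in the design separate such a ligand from PCSK9, and the ligand and the protein cannot be told apart here.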

How the results depend on the processing

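The fits with the replicate block and 1 replicate number left out and with the log2 Rn45s share as a covariate were chosen after the data had been seen, and all other alternatives were fixed beforehand. Of 57 called genes named in the text, 0 reversed under any alternative, 28 kept their call in every alternative fitted on 8 libraries and 25 kept it with each library left out in turn, Il1b, Irg1, Cxcl2, Olr1, Tlr2 and Nfkbia among these 25. The counts of higher and lower genes were 232 and 72 with arrayWeights, 62 and 2 without the trend, 834 and 679 with the replicate block, and 66 and 4 with the Rn45s covariate, against 111 and 17; the cause was not tested. With the replicate block the list call that was lost was heat shock and the one gained was lysosome, no named gene lost its call, and uncalled genes that gained one are given beside their values. The number of called lists was 1 with an estimated correlation and 6 with fry, against 13. It was 0 with both the block and an estimated correlation, and 8 with both the block and fry. With 1 library left out, 45 to 140 genes were higher, 2 to 20 lower and 12 to 16 lists called, fits that have fewer libraries. With the block and replicate number 1, 2, 3 or 4 left out, 411, 480, 683 and 660 genes were higher, 187, 293, 486 and 557 were lower, and 13 to 15 lists were called. Scaling moved the median of all tested genes by at most 0.02 on the log2 scale. Uncalled genes that changed sign under quantile normalization were Mpeg1 (0.02), Pkm (0.01) and Psap (0.05), and with the Rn45s covariate Cd22 (0.25), Ctsd (0.02), Ldlr (0.06), Mertk (0.03), Psap (0.05), Rn45s (0.01, by construction) and the lysosome and autophagy list (camera adjusted p = 0.806), and the cause was not tested for the others. With 1 library left out, the log2 fold change ran from -0.27 to 0.02 for Apoe, -0.30 to 0.10 for Cd22, -0.55 to 0.27 for Vldlr, -0.94 to 0.44 for Col1a1, -0.01 to 0.28 for Lrp8, -0.14 to 1.78 for Krt8 and -0.15 to 0.08 for Ldlr. With the block it was 0.13 and 0.17 for Vldlr without replicate number 2 and 3, and -0.31 for Krt8 without number 4. The planned count models, edgeR and DESeq2 on recovered reads, were not run. Every positive value was a whole multiple of its library's step, but the steps of control library 4 and PCSK9 libraries 2 and 4 (1.0049, 1.0065 and 0.9888) lie so near 1 that the fixed rule for accepting recovered reads treats them as rounding. At 18068687 to 21263385 reads per library, genes with means under 10 were left untested, Il6, Nos2 and Il12b among them.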

Other observations

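The readings in left-out pairs, the blocked fit without replicate 4, the search for genes high in 1 library, the median rise without PCSK9 library 4 and the tests of mesothelial, epithelial and pseudogene transcripts were chosen after the values had been seen, as were the genes named here that the naming rule does not give, and the other fits were planned.

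With the replicate number as a block, further members of the cytokine, chemokine, classical activation and adhesion lists were called. Il1a, the other interleukin-1 cytokine gene, was higher in 4 of 4 pairs, at 87.0 ± 54.3 in controls and 192 ± 120 with PCSK9 (2.16-fold, limma adjusted p = 0.402 without the block and 3.93e-05 with it). Ptgs2, which encodes cyclooxygenase-2, stood at 11.97 ± 5.85 and 40.4 ± 13.3 (3.43-fold, 0.117 and 0.000878), and the adhesion molecule gene Vcam1 at 11.6 ± 4.02 and 45.03 ± 21.5 (3.47-fold, 0.077 and 0.00106). The formyl peptide receptor genes Fpr1 and Fpr2 were 6.68-fold and 5.13-fold higher (0.253 and 0.000514 for Fpr1, 0.17 and 0.00137 for Fpr2), the chemokine gene Cxcl10 8.20-fold (0.11 and 0.00513) and the costimulatory receptor gene Cd40 2.05-fold (0.204 and 0.000988), each in 4 of 4 pairs. Fpr2, Cxcl10 and Cd40 were also called with limma arrayWeights and no block (limma adjusted p = 0.0297, 0.042 and 0.0439). With a pseudocount of 5 the fold was 3.97 for Fpr1, 3.33 for Fpr2 and 3.42 for Cxcl10, and with 0.5 it was 7.57, 5.61 and 11.8. Several genes seen at high levels in classical activation by bacterial products stayed near 0, while Il1b, Tnf and Irg1 from the same lists rose. The dose and duration are not given, so these low values cannot tell a bacterial ligand from PCSK9. Il6 had means of 0.52 in controls and 0.74 with PCSK9, Nos2 was listed at 0 in all 4 controls and at 0.9 to 6.0 with PCSK9, and Il12b had means of 0.51 and 1.94.

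The lists of cholesterol synthesis, cholesterol efflux and fatty acid genes did not pass with the block (camera adjusted p = 0.622, 0.687 and 0.316). Among single genes, Abca1, which exports cholesterol, was higher in 4 of 4 pairs, at 5749 ± 1970 in controls and 9316 ± 2487 with PCSK9 (1.65-fold, limma adjusted p = 0.317 without the block and 1.74e-06 with it). The scavenger receptor gene Msr1 was 1.20-fold higher (0.472 and 0.000217). The lipid droplet gene Plin2 stood at 0.885-fold (0.592 and 0.0073), the receptor gene Trem2 at 0.905-fold (0.299 and 0.0123) and Tfeb, a regulator of lysosomal genes, at 0.848-fold (0.331 and 0.00213), each lower in 4 of 4 pairs. Rn45s was also lower in 4 of 4 pairs (0.445-fold, 0.612 and 0.0438). Its log2 ratios in pairs 1 to 4 were uneven, at -3.2, -0.62, -0.07 and -0.78. With 1 library left out its log2 fold change ran from -1.87 to -0.80.

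The response was read again in pairs that had no part in calling the genes, although the filter on the mean used all 8 libraries. Genes called higher in the blocked fit on 3 pairs were higher in the left-out pair for 408 of 411 genes in pair 1, 468 of 480 in pair 2, 639 of 683 in pair 3 and 619 of 660 in pair 4. Genes called lower were lower there for 186 of 187, 289 of 293, 449 of 486 and 508 of 557. The median log2 ratio of the higher genes in the left-out pair was 0.39, 0.44, 0.21 and 0.31.

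PCSK9 library 4 held a set of transcripts at higher levels than every other library. This set of 123 genes stood above 20 and at least 4-fold above every other library, against 0 or 1 in each other library. Together they made up 0.06% of the total of PCSK9 library 4, a share that leaves out extra RNA from genes under these cutoffs. PCSK9 library 4 also had the most genes above 0, at 15005 against at most 14417 elsewhere. The 123 genes were led by Spon1 at 720, Cdh6 at 642, Arhgap29 at 533 and Krt7 at 436, against at most 3.0, 1.0, 95.6 and 22.1 elsewhere. Without this library the unblocked fit kept 79 of the 111 higher genes, with a median log2 rise of 0.91 against 0.89 with all libraries (median SE 0.14 and 0.13), and removing any other library kept 45 to 100. The blocked fit without replicate 4, which called 660 genes higher, kept 111 of the 111. Blocked fits called many more genes, and no named gene lost its call in them whichever replicate number was left out. The count of 111 thus says little about this library in particular. The near-equal rise in the unblocked fit argues against this RNA as the cause, and the 32 calls that ended there did so with fewer libraries.

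Of the sources weighed for the extra RNA in PCSK9 library 4, mesothelial cells are argued against, since the 4 mesothelial markers other than keratins with a mean of at least 10 had a median log2 difference of 0.16 to the highest other library (interquartile range -0.35 to 0.53), although 2 of these were highest in this library, Upk1b at 90.0 against at most 46.3 and Wt1 at 110.8 against at most 84.0. Epithelial cells may be a source, as a hypothesis. Over the 10 listed epithelial markers whose values had not been seen, the median log2 excess was 2.52, with 7 at 2 or more. These 7 were low, from 4.9 for Cldn4 to 22.7 for Pkp3 in this library, and no minimum mean was set as for the mesothelial markers. The most abundant of the 10, Spint1 and Lsr, showed no such excess (56.4 against at most 54.4, and 41.5 against at most 53.3). Of the 10, 2 were in the set of genes high in this library alone. The most abundant of all 20 listed were Krt7 at 436, Krt8 at 398, Krt18 at 292 and Dsp at 224. Of these 20 markers, 6 also stood above 20 in another library and 4 are in the mesothelial list, and no sort of the cells is stated that would remove such cells. Reads of another species may be a source too, since annotated pseudogenes were 11 of 119 annotated genes (9.2%) in the set against 1.34% of other genes (odds ratio 7.5, Fisher's exact p = 5.77e-06). These other genes stood above 20 in this library and at up to 95.6 elsewhere. They were not matched to the set for low levels in the other libraries, so the excess may follow from those low levels and not from the source. Both sources remain open.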
